A study of Mus musculus with 4 samples.

How the data were processed

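RNA was measured in superficial-zone articular cartilage of the medial femoral condyle from 2 C57BL/6J mice, M04 and M05, 8 weeks after surgery, with a DMM knee and a sham knee from each animal. Per the labels' protocols, total RNA was treated with DNase, poly(A) RNA was selected, and libraries were sequenced as single-end reads of 100 bases on a HiSeq 2500. The genome build was GRCm39 (mm39) per the submitters' processing notes. The aligner and the counting method are not given in the sources used here, nor is it stated whether the libraries kept strand, so overlapping and antisense genes cannot be told apart in these counts. The names of the samples, their treatment field and the columns gave the group and the mouse. The free-text descriptions of both sham samples speak of a DMM-operated knee, against their titles and treatment field, which were followed. The genotype is given in 2 ways: wild type in the sample labels, and knockout for M05 in the series' design text. No genotype was inferred from the data.

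The deposited count table holds estimated counts per gene, which need not be whole: 9.21% to 10.9% of the values in a library were not whole numbers. The table lists each library in 2 columns, and all 24421 values of the second column equalled those of the first in every library, so each library was counted once. The deposited FPKM table holds FPKM values that the authors made, scaled for transcript length and depth. It served only for alternatives and for comparing the tables gene by gene, on log2(value + 0.1). Rows with the same counts in all libraries were found for 50 genes in 21 groups with over 100 counts, such as the beta globins, so some reads are counted in more than one row. Genes are named as in the files, and 24421 rows were listed. Per library the total count was 12712425 to 19336628, and 15472 to 15910 genes had a count above 0. For a share of counts, a 95% Wilson interval was computed, and a count of 0 allows up to 3 counts.

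Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (13103 of 24421), libraries were scaled by TMM, and a quasi-likelihood model with robust moderation was fitted with the mouse and the surgery as terms. Adjusted p-values are Benjamini-Hochberg values over all genes tested, separately for the surgery and for the mouse, with a threshold of 0.05 and no limit on the fold change. Standard errors are the size of the log2 fold change divided by the square root of F. The mouse is a block because the labels state that both knees are of the same animal, and the deviations of same-mouse libraries from the group means correlated at 0.13 across genes. The fit leaves 1 residual degree of freedom, which is the difference between the responses of the mice. The prior degrees of freedom were infinite for 10879 genes (83.0%). For these genes the spread behind a p-value came from the trend across genes, not from the gene's own difference between the mice. Their p-values thus do not measure how far the responses of the 2 mice differ. P-values for M05 against M04 compare 2 animals, not genotypes. Per mouse, log2 ratios were taken from TMM-normalised CPM with a prior count of 2, without a test.

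Gene lists (31, with 396 genes, of which 376 were found, 5 under an older or other name) and the rule for named genes were fixed before the data were examined. The lists cover cartilage matrix and chondrocyte identity, the superficial zone, proteases and their inhibitors, hypertrophy, fibrous matrix, inflammation, interferon, TGF-beta and BMP, Wnt, glycolysis, oxidative phosphorylation, antioxidant genes, autophagy, the unfolded protein response, senescence, proliferation, the clock, immediate-early genes and ribosomal proteins. Others mark osteoblasts, osteoclasts, macrophages, granulocytes, erythroid cells, lymphocytes, endothelium, muscle, adipocytes and fibroblasts. A list of the 13 mitochondrially encoded genes was not tested, because none of their symbols is among the row names used here. The 30 other lists, with at least 3 tested members each, were tested by camera in limma 3.58.1 with a preset correlation of 0.01. Where the members of a list vary together by more than this preset value, its p-values are too small. Beside it, camera was run with an estimated correlation, and fry was run. The estimated form rests on the 1 residual degree of freedom, and no list had an unadjusted p under 0.05 with it in either comparison. It could thus hardly pass any list and decides nothing for or against one. Per mouse, a list's median ratio was placed among 10000 random lists of the same size matched on mean expression.

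Named genes were chosen as follows, leaving out unnamed gene models. For DMM against sham these are the 10 highest and 10 lowest fold changes past the threshold with the same sign in both mice and a mean of at least 5 CPM. Missing places went to the smallest p-values. For M05 against M04 the 8 highest and 8 lowest were taken in the same way. For each list past camera or of the tissue kind, up to 4 members with the smallest p were taken, together with Prg4, Acan, Col2a1, Col10a1, Mmp3, Mmp13, Adamts5, Sox9, Timp1 and Runx2. Per mouse, the 5 highest and 5 lowest ratios among genes with a mean of at least 10 CPM in that mouse were taken, and the 5 largest differences between the mice in each direction. The 5 most abundant genes of each library and 5 sex-linked genes complete the rule. Some genes that the rule names are not reported here.

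The functions were tested on simulated counts drawn from the real means and library sizes for 13103 genes, in 5 runs with 100 genes changed by each fold size. For surgery, 69.6% of the genes changed by 1 log2 unit and 96.8% of those changed by 2 were recovered, and 3.59% of the calls were false. For the mouse the values were 69.4%, 94.8% and 3.98%. A shifted list was called in 5 of 5 runs for each comparison, and 0 other lists were called. Genes were drawn independently with their spread on the fitted trend, and the changed genes had a mean above 2 log2 CPM. The runs held no unequal tissue and no difference in response between the mice. They thus check the functions and do not measure the false calls in the real data.

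Alternatives were other scalings (RLE, upper quartile, library totals), other filters, the fit without the block or without the surgery term, each library left out in turn, DESeq2 1.42.0, limma-voom, limma on FPKM with pseudocounts of 1 and 0.1, a threshold of 0.1, the split of the DMM library of M04 and the sham library of M05 against the other 2 without other terms, and library sizes without haemoglobin and ribosomal protein genes (114 rows). That split tests whether the responses of the mice differ, with the effects of mouse and surgery left in the spread. Added after seeing the data were scaling on the cartilage list, thinning to the smallest total, offsets for transcript length and GC content, and limma with a finite prior. Lengths and GC content come from mouse reference transcripts of GENCODE vM21, on another build than the files, matched by symbol for 99.3% of genes tested. No coordinates are given for that reason.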

Results

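Messenger RNA was counted in 4 libraries of superficial-zone cartilage, the surface layer of the joint, from the medial femoral condyle of the mouse knee 8 weeks after surgery. The knees belonged to 2 mice, M04 and M05. Each mouse gave a sham-operated knee and a knee with destabilization of the medial meniscus (DMM), in which the ligament holding the meniscus is cut and osteoarthritis follows from joint instability. This made 2 DMM and 2 sham libraries, with 1 library per knee and 1 mouse behind each pair. The total count was 12903678 in the sham and 13262655 in the DMM library of M04, and 19336628 in the sham and 12712425 in the DMM library of M05. The sample labels call both mice wild type, whereas the series' design text calls the samples of M05 knockout and names no gene. Differences between M05 and M04 are therefore reported as differences between 2 animals.

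Transcripts of blood and marrow cells made up a large part of every library, and cartilage transcripts a small part. The genes with the highest counts were the same in all 4 libraries, namely Hba-a1, Hba-a2, Hbb-bs, Hbb-b1 and Hbb-bt, all of them haemoglobin chains. The 10 haemoglobin rows held 30.3% of the counts in the sham and 25.7% in the DMM library of M04, and 35.3% and 29.4% in those of M05. Hbb-b1 and Hbb-b2 repeated the counts of Hbb-bs and Hbb-bt, and without these 2 rows the shares were 25.1%, 20.7%, 27.7% and 24.4% in the same order. Hba-a1 and Hba-a2 had nearly equal counts too, with 9.941% and 9.940% in the sham library of M04. Both rows remain in these shares, which are too high if the same reads were counted in both. Genes of neutrophils and marrow granulocytes, such as S100a8 and Camp, held 4.13% and 4.44% in M04 and 5.81% and 5.43% in M05. The fibrous matrix list, which includes Col1a1 and Col1a2, held 1.46% and 1.92% in M04 and 0.988% and 1.25% in M05. Osteoblast and osteocyte genes held 0.159% and 0.214% in M04 and 0.162% and 0.195% in M05. The 25 genes for cartilage matrix and chondrocyte identity held 0.751% of the counts in the sham library of M04 (95% Wilson interval 0.746 to 0.756) and 0.936% in its DMM library (0.931 to 0.941). In M05 they held 0.192% in the sham library (0.190 to 0.194) and 0.621% in the DMM library (0.617 to 0.625). The sham library of M05 thus had the lowest cartilage share of the 4. These intervals cover counting error only.

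**Figure D1:**
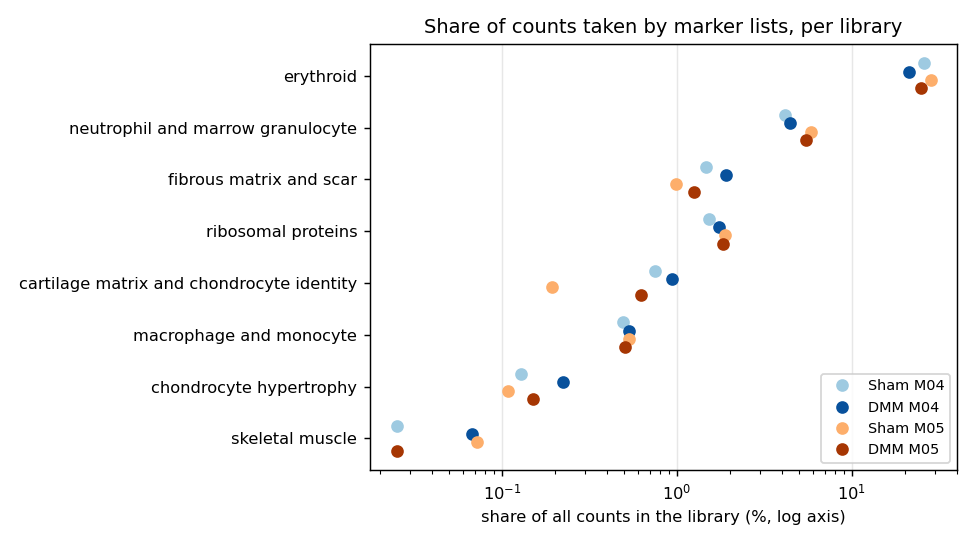
Share of all counts in a library (%, log axis) taken by 8 gene lists; each point is 1 library, coloured by mouse and surgery. The cartilage list lies at 0.192% in the sham library of M05 and between 0.621% and 0.936% in the others, and the skeletal muscle list is high in the DMM library of M04 and the sham library of M05.

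The sex-linked transcripts were alike in the 4 libraries. Xist, the transcript of the inactive X chromosome, had 0 counts in each, which allows up to 0.236 CPM in the shallowest library and 0.155 CPM in the deepest. The Y-linked genes were counted in all of them, with Ddx3y between 5.66 and 12.6 CPM, Uty between 1.73 and 3.95 CPM, Kdm5d between 3.36 and 5.66 CPM and Eif2s3y between 20.8 and 27.1 CPM.

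The first comparison asked how cartilage of DMM knees differs from that of sham knees. Of 13103 genes tested with the mouse as a block, 83 were higher and 2 were lower past an adjusted p of 0.05, and all 85 had moved in the same direction in both mice. Col3a1, a collagen of fibrous tissue and repair, rose by 2.08 on the log2 scale (SE 0.16, adjusted p = 1.87e-34), from 75.6 to 394 CPM in M04 and from 43.9 to 150.0 CPM in M05. Dpt, which encodes dermatopontin, a matrix protein that binds decorin, rose by 2.09 (SE 0.32, adjusted p = 9.47e-08). Htra1, a secreted serine protease that cleaves matrix proteins, rose by 1.38 (SE 0.20, adjusted p = 4.30e-09). Col10a1, the collagen of hypertrophic chondrocytes, rose by 1.04 (SE 0.15, adjusted p = 2.51e-08), and Timp1, an inhibitor of metalloproteases, by 1.12 (SE 0.19, adjusted p = 4.28e-06).

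The other 7 of the 10 largest increases at a mean of at least 5 CPM were of several kinds. Kcna6, a potassium channel subunit, rose by 1.71 and Nt5e, the surface enzyme that makes adenosine from AMP, by 1.54. Sbsn rose by 1.52, Sod3, the extracellular superoxide dismutase, by 1.43 and Igfbp6, a binding protein for insulin-like growth factors, by 1.39. Serpina1b rose by 1.41, but it belongs to a family of near-identical genes whose reads can be split in more than one way, so its value is uncertain. The same holds for the embryonic globin Hbb-bh1, at 1.39. It also turned to -4.31 when the DMM library of M05 was left out, in a fit without the mouse term. Only Stam (-1.24, SE 0.34), an adaptor in endosomal sorting, and Ago2 (-0.65, SE 0.18), the slicer of RNA interference, were lower past the threshold. Both calls were kept with a filter of at least 5 CPM on average, without robust moderation and at an adjusted p of 0.1, and were lost in all 4 fits that leave out 1 library and in every other setting. The next lowest p-values among genes with negative fold changes belonged to Slfn8 (-0.99), Casd1 (-1.07), Nanp (-0.74), Xpo1 (-0.60), Ppp1cb (-0.52), Tfec (-0.84), Nin (-0.54) and Cd209f (-1.06). None of these 8 passed the threshold, with adjusted p-values from 0.052 for Slfn8 to 0.17 for Cd209f.

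**Figure D2:**
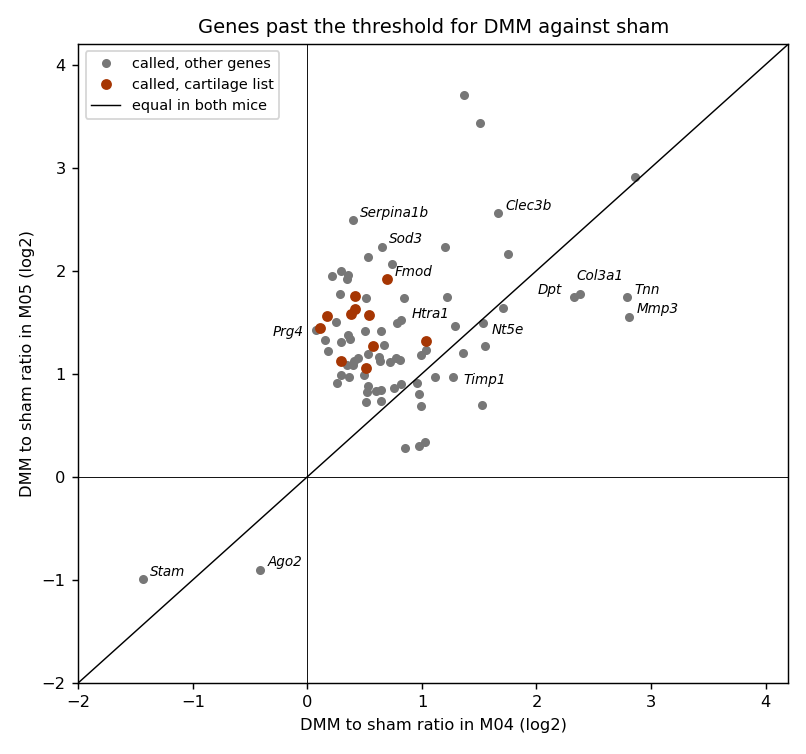
DMM to sham ratio in M04 (x axis, log2) against that in M05 (y axis, log2) for the 85 genes past the threshold; each point is 1 gene, and genes of the cartilage list are drawn in red-brown. Most points lie above the line of equal ratios: the 83 higher genes have a median ratio of 0.64 in M04 and 1.32 in M05.

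The cartilage list passed camera as higher in DMM knees (adjusted p = 4.37e-42). This p-value takes the preset correlation of 0.01 between genes, while the estimate for this list was 0.84. With the estimated correlation the list's adjusted p was 0.696, but that form rests on 1 residual degree of freedom and could hardly pass any list. By fry the list's adjusted p was 0.603. All 25 members were tested. 11 were higher past the threshold and none was lower. Adjusted over the list alone, 17 were higher and 1 was lower. Fmod, a collagen-binding proteoglycan, rose by 1.30 (SE 0.16), Col9a3 by 1.04 (SE 0.16), Comp by 1.02 (SE 0.16) and Col9a1 by 0.97 (SE 0.16). Without the sham library of M05 these 4 stood at 0.49, 0.24, 0.36 and 0.19 in this order, and without that of M04 at 2.16, 1.94, 1.69 and 1.80. These and the other fits that leave out a library have no mouse term, so the difference between the mice enters their values. The chief cartilage genes themselves did not pass, and their ratios differed between the mice: Col2a1 had a log2 fold change of 1.05 (SE 0.27, adjusted p = 0.086), Acan of 1.17 (SE 0.96, adjusted p = 1.0) and the transcription factor Sox9 of 0.99 (SE 0.38, adjusted p = 0.50). Col2a1 went from 3343 to 3822 CPM in M04 and from 726 to 2739 CPM in M05. Of the superficial-zone list, 7 genes were tested and 1 was higher, Prg4, which encodes the lubricant lubricin: it rose by 0.74 (SE 0.18, adjusted p = 0.036), with ratios of 0.07 in M04 and 1.42 in M05. Without the sham library of M05, in a fit that mixes in the difference between the mice, Prg4 stood at -0.11. Clu (0.56), Vit (0.56) and Thbs4 (0.42) did not pass. Adjusted over the list alone, 2 were higher. The list passed camera (adjusted p = 2.45e-05) but had an adjusted p = 0.696 with an estimated correlation.

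The lists for fibrous matrix, hypertrophy, proteases and protease inhibitors passed camera as higher in DMM knees, but had an adjusted p = 0.696 each with an estimated correlation. In the fibrous matrix list, 17 genes were tested and 3 were higher, namely Col3a1, the cell-adhesion protein fibronectin (Fn1, 0.74, SE 0.16) and connective tissue growth factor (Ctgf, 0.58, SE 0.16). Without the sham library of M05, Fn1 stood at 0.24 and Ctgf at 0.05. Loxl2, a collagen cross-linking enzyme, did not pass (0.67, adjusted p = 0.105). Of 15 hypertrophy genes, 4 were higher: Col10a1, the alkaline phosphatase Alpl (0.72, SE 0.15), the parathyroid hormone receptor Pth1r (0.62, SE 0.15) and bone sialoprotein Ibsp (0.56, SE 0.16). Runx2, the regulator of hypertrophy, had a fold change of 0.12 (adjusted p = 1.0). Adjusted over the list alone, 7 were higher in each of these 2 lists. Of 15 matrix-degrading proteases, Htra1 and stromelysin Mmp3 were higher, Mmp3 by 2.46 (SE 0.64, adjusted p = 0.028) from a low level of 0.741 to 6.02 CPM in M04 and from 0.469 to 1.64 CPM in M05. The collagenase Mmp13 (0.53, adjusted p = 0.103), the gelatinase Mmp2 (0.50, adjusted p = 0.178) and the aggrecanase Adamts5 (-0.38, adjusted p = 1.0) did not pass. Adjusted over the list alone, 6 proteases were higher. Of 8 inhibitors only Timp1 was higher, over all genes and adjusted over the list alone, while Timp2 (0.35) and Serpine2 (0.29) did not pass. Camera gave adjusted p = 7.73e-17 for fibrous matrix, 6.75e-12 for hypertrophy, 2.32e-06 for proteases and 3.10e-06 for inhibitors.

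The Wnt, osteoblast and fibroblast lists passed camera as higher and the erythroid list as lower in DMM knees. With an estimated correlation the adjusted p was 0.696 for the Wnt and erythroid lists and 0.717 for the osteoblast and fibroblast lists. Of 12 Wnt signalling genes 1 was higher, the secreted inhibitor Wif1 (0.64, SE 0.17). Wisp2 (0.73), the Wnt-inactivating enzyme Notum (1.63) and the ligand Wnt5a (2.28) did not pass, and adjusted over the list alone 3 were higher. Of 11 osteoblast and osteocyte genes 2 were higher, Alpl and Ibsp, which are also in the hypertrophy list. Both were also the only ones adjusted over the list alone, and Ifitm5 (0.41) and Sp7 (0.34) did not pass. Of 7 genes of synovial and tendon fibroblasts 1 was higher, Clec3b (2.19, SE 0.47), also the only one adjusted over the list alone, while Thy1 (0.36), Mfap5 (1.08) and Pi16 (-0.13) did not pass. None of the 7 erythroid genes passed, over all genes or adjusted over the list alone, but all had negative fold changes, among them Hbb-bs (-0.48), Hbb-bt (-0.38) and Hba-a1 (-0.32). Camera's adjusted p was 0.000980 for Wnt signalling, 0.00756 for osteoblasts, 0.0310 for fibroblasts and 2.45e-05, in the direction of lower values, for the erythroid list.

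The remaining 20 tested lists did not pass camera. The nearest were the osteoclast list (higher) and the proliferation list (lower), each with an adjusted p of 0.0593. Then came adipocytes (0.108), TGF-beta and BMP signalling (0.121), cell-cycle arrest and senescence (0.195), glycolysis and hypoxia (0.286), macrophages and monocytes (0.297) and autophagy (0.364). Inflammatory mediators and the interferon response each stood at 0.439. Adjusted p-values were above 0.5 for neutrophil and marrow granulocyte genes, oxidative phosphorylation, the circadian clock, ribosomal proteins, antioxidant and iron-dependent death genes, lymphocytes, skeletal muscle, endothelium, immediate-early and heat shock genes, and the unfolded protein response. The antioxidant list had a median of -0.02 and a mean of 0.09.

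The count of genes rests on a fit with 1 residual degree of freedom, in which the spread of 83.0% of genes was taken from the trend across genes. edgeR without the mouse term gave 0 genes past the threshold (322 at an unadjusted p under 0.05, smallest adjusted p 0.460, against 681 with the term). DESeq2 with both terms gave 13, and limma on log2(FPKM + 1) gave 1, Snord33, as lower. In fits of 3 libraries without the mouse term, 0 passed without the DMM library of M04, 4 without the DMM library of M05 (Col3a1, Dpt, Tnn and Postn), 121 without the sham library of M04 and 1 without the sham library of M05, Hbb-y, as lower. Of the genes named in this paragraph, Snord33, Tnn, Postn and Hbb-y were chosen after their values were seen. Of the 28 named genes past the threshold, 26 kept their sign in all 4 of those fits, and Prg4 and Hbb-bh1 did not, while in 20 of the 28 the fold change moved by over 1.5 times in at least 1 fit.

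The second question was how far the 2 mice responded alike. With the mouse and the surgery both in the model, no degree of freedom is left to test a difference between the responses. Without these terms, the DMM library of M04 and the sham library of M05 were set against the other 2, which leaves 2 degrees of freedom and counts any effect of mouse or surgery as spread. Of 13103 genes 2 passed, Mb, which encodes myoglobin, and Acta1, the actin of skeletal muscle, each with an adjusted p of 0.0342. The ratios in M04 and M05 were 3.65 and -3.76 for Mb and 1.59 and -1.99 for Acta1. Across the 13103 genes the DMM to sham ratios of M04 and M05 had a Pearson correlation of -0.04 and a Spearman correlation of -0.03. Genes are not independent replicates, so these 2 correlations only describe the 4 libraries. Among the 83 higher genes, 53 had a log2 ratio of at least 0.5 in both mice, 27 had one below 0.5 in M04, and in 40 the log2 ratio in M05 was over 2 times that in M04. Among genes named above, the ratios were 2.38 and 1.77 for Col3a1, 2.33 and 1.74 for Dpt, 1.29 and 1.47 for Htra1, 1.53 and 1.49 for Nt5e, 1.27 and 0.97 for Timp1 and 1.12 and 0.97 for Col10a1, in M04 and M05 in turn. They were 0.49 and 0.99 for Fn1 and 0.26 and 0.91 for Ctgf, and 12 of the 17 fibrous matrix genes had the same sign in both mice.

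The ratios of cartilage genes were larger in M05. The median ratio of the cartilage list was 0.26 in M04 and 1.56 in M05, and in each mouse it lay above all 10000 random lists matched on expression. The superficial-zone list had a median of 0.15 in M04 (percentile 93.9) and 0.63 in M05 (percentile above 99.9). Acan had ratios of 0.26 and 2.11, Prelp 0.08 and 2.08, and Cilp 0.26 and 2.19. Serpina1b (0.40 and 2.49) and the glycoprotein gene Gpnmb (-0.27 and 1.56) showed the same order, and these 5 were the genes with a mean of at least 10 CPM over all libraries whose ratio in M05 most exceeded that in M04. Among genes with a mean of at least 10 CPM in M05, the largest ratios there were those of Serpina1b, Sod3 (2.23), Cilp, Anxa8 (2.14) and Acan. Other lists were higher in M04: the median was 0.55 in M04 and 0.13 in M05 (percentile 92.1 of random lists) for proteases, 0.89 and 0.06 for Wnt signalling, 0.51 and 0.21 for hypertrophy, 0.45 and 0.20 for fibrous matrix, 0.43 and 0.30 for protease inhibitors, 0.33 and 0.03 for osteoblasts and 0.20 and 0.02 for fibroblasts. The erythroid median was -0.34 in M04 and -0.17 in M05. Mmp13 had a ratio of 1.02 in M04 and 0.04 in M05.

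Skeletal muscle genes had ratios of opposite sign in the 2 mice. The median ratio of the muscle list was 1.5 in M04, above all 10000 random lists, and -1.80 in M05, below all of them. Myh1, a fast myosin heavy chain, had ratios of 3.74 and -4.0, Mybpc2 of 2.11 and -1.63 and Pvalb, the calcium buffer of fast fibres, of 1.70 and -1.89. These 3, with Col3a1 and Dpt, had the largest ratios in M04 among genes with a mean of at least 10 CPM there. The lowest in M05 under the same limit, which Myh1 missed in that mouse, were Casq1 (-2.79), Acta1 (-1.99), Des (-1.91), Pvalb and Ckm (-1.82). With the limit set on the mean of all libraries, Myh1, Mybpc2, Pvalb, Acta1 and Des were the 5 genes whose ratio in M05 lay furthest below that in M04. Among tested genes with a mean of at least 10 CPM in M04, the lowest ratios there belonged to Slfn8 (-1.25), Zwilch (-1.10), Trim14 (-1.07), Trpm2 (-0.94) and Plekhg2 (-0.91).

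**Figure D3:**
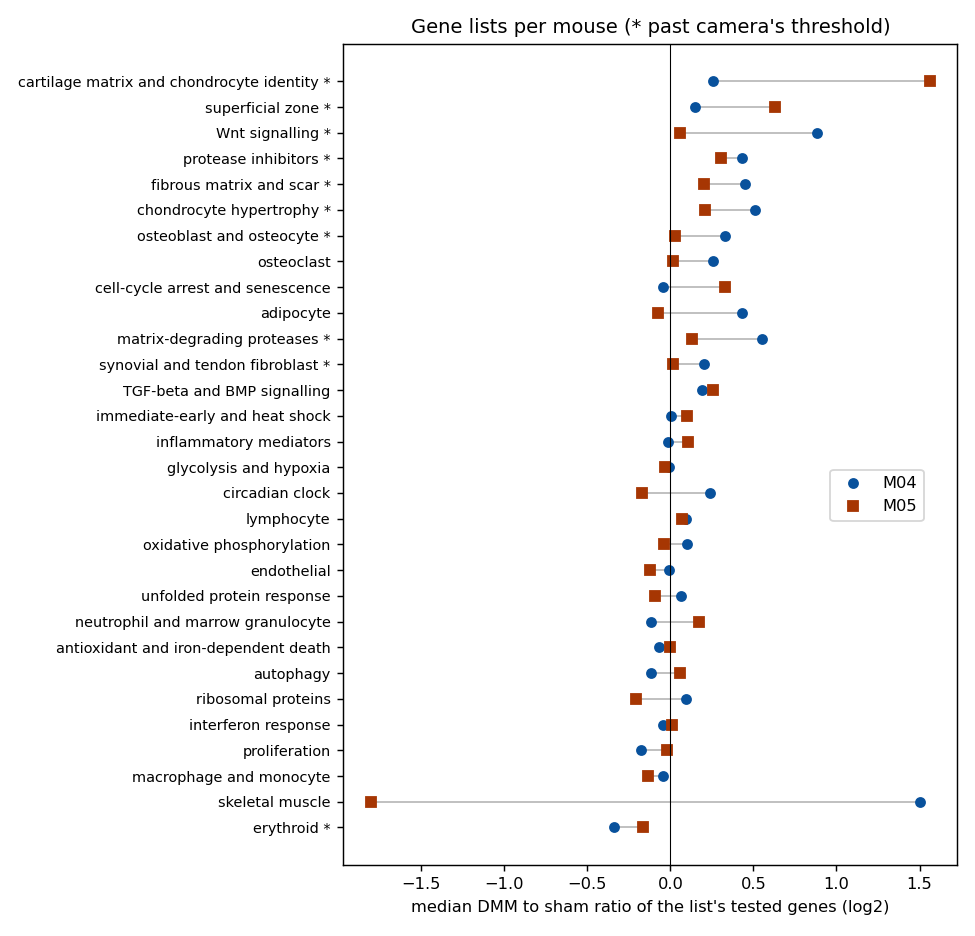
Median DMM to sham ratio (x axis, log2) of the tested genes of each of the 30 gene lists, with a circle for M04 and a square for M05; a star marks lists past camera's threshold. The cartilage list lies at 0.26 in M04 and 1.56 in M05, and the skeletal muscle list at 1.5 in M04 and -1.80 in M05.

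The third comparison set mouse M05 against mouse M04, with the surgery as a term. The cartilage list passed camera as lower in M05, with 12 of 25 genes lower, and the granulocyte list as higher, with 2 of 9 genes higher. With an estimated correlation both had an adjusted p = 0.689, and by fry it was 0.532 for the cartilage and 0.180 for the granulocyte list. 126 genes were higher and 215 lower past the threshold, and 340 of the 341 had the same direction in sham and in DMM knees. Col2a1, the main cartilage collagen, had a log2 difference of -1.34 (SE 0.27, adjusted p = 0.00535). Its differences were -2.20 in sham and -0.48 in DMM knees. The largest decreases past the mean count limit were those of Col16a1 (-1.63), the RNA export factor Alyref (-1.55), Thbs3 (-1.44), the collagen receptor Ddr2 (-1.36), Col12a1 (-1.34), Col2a1, the transcription factor Fli1 (-1.34) and Gatad2b (-1.31). The largest increases were those of Hbb-bh1 (7.02), Chil4 (2.0), Cd209f (1.21), the ribosomal RNA precursor Rn45s (1.18), Coa6 (1.11), Wfdc21 (1.02), Rps4l (1.02) and Slc7a14 (0.98).

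The 2 largest of these increases came from rows whose reads can be shared with related genes. Hbb-bh1 had 0 and 4.33 counts in the sham and DMM libraries of M04 and 183 and 318 in M05. In the deposited FPKM table it stood at 0, 0.656, 0.144 and 1.02. Chil4 had 285 and 662 counts in M04 and 2054 and 1544 in M05, but at most 0.0572 FPKM in any library. Of 13093 genes in both tables, 188 differed between them by over 1 log2 unit in at least 1 library, and 11 of the 341 genes were among these.

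Of 25 cartilage genes 12 were lower and none higher, with Col9a3 at -1.17 (SE 0.16), Fmod at -1.05, Col9a1 at -1.0 and Col11a2 at -0.95. Without the sham library of M05 these 4 stood at -0.42, -0.14, -0.23 and -0.54 in this order. This fit, like the others below that leave out a library, has no surgery term, so the effect of surgery enters its values. Adjusted over the list alone 15 were lower. The median difference was -1.36 in sham knees and -0.39 in DMM knees. Of 17 fibrous matrix genes 6 were lower, 10 adjusted over the list alone, among them Fn1 (-0.80), Ctgf (-0.77), Fbn1 (-0.89) and Col3a1 (-1.10). Col3a1 stood at 0.35 without the DMM library of M04. In the superficial-zone list 4 of 7 genes were lower, also adjusted over the list alone: Prg4 (-1.06), Abi3bp (-1.23), Thbs4 (-0.74) and Clu (-0.56). Clu stood at -0.00 without the sham library of M05. The hypertrophy list had 4 of 15 lower, over all genes and over the list alone: Panx3 (-1.25), Col10a1 (-0.78), Alpl (-0.52) and Pth1r (-0.51). Camera's adjusted p was 2.66e-25 for cartilage, 1.50e-10 for fibrous matrix, 6.10e-06 for the superficial zone and 0.000804 for hypertrophy, and with an estimated correlation the adjusted p was 0.689 for each. The cartilage share of all counts, as given above, was lower in M05 in both kinds of knee.

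The granulocyte, ribosomal protein, oxidative phosphorylation and erythroid lists passed camera as higher in M05, but each had an adjusted p = 0.689 with an estimated correlation. Of 9 granulocyte genes tested, S100a8 (0.95, SE 0.22) and S100a9 (0.88, SE 0.23), the abundant calcium-binding proteins of neutrophils, were higher and none was lower, with 4 higher adjusted over the list alone. Camp (0.60) and Retnlg (0.52) did not pass. Of 12 ribosomal protein genes Rps23 (0.59) was higher, 10 adjusted over the list alone, and Rps18 (0.54), Rpl32 (0.49) and Rps9 (0.50) did not pass over all genes. Of 15 genes of oxidative phosphorylation Cox7b (0.59) and Cox6c (0.55) were higher, 9 adjusted over the list alone, and Uqcrq (0.46) and Ndufa1 (0.47) did not pass. No erythroid gene passed either count, with Hbb-bt at 0.56, Hbb-bs at 0.44 and Hba-a2 at 0.41. Camera's adjusted p was 7.78e-09 for granulocytes, 5.48e-10 for ribosomal proteins, 9.31e-08 for oxidative phosphorylation and 0.00153 for the erythroid list. Called genes differed in length: the median mean-transcript length was 784 bases for the higher, 2719 for the lower and 1766 for all genes.

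A further 4 lists passed camera as lower in M05, with 1 or 2 genes past the threshold in each, but had an adjusted p = 0.689 each with an estimated correlation. In the adipocyte list, the complement factor and adipokine Cfd (-0.92) was lower as 1 of 5 genes, 2 adjusted over the list alone, with Cidec (-1.25), Plin1 (-1.27) and Adipoq (-0.19) not past the threshold. In the circadian clock list Per1 (-1.04) was lower as 1 of 10, 2 over the list alone, with Nr1d1 (-0.55), Nr1d2 (-0.92) and Tef (-0.32) not past it. Igfbp5 (-0.72) was lower as 1 of 7 genes for cell-cycle arrest and senescence, 2 over the list alone, with Igfbp7 (-0.40), Igfbp3 (-0.52) and Mdm2 (-0.20) not past it. The endothelial adhesion gene Cdh5 (-0.99) and the VEGF receptor Kdr (-0.92) were lower as 2 of 8, the same count over the list alone, while Pecam1 (-0.27) and Tie1 (-0.30) did not pass. Camera's adjusted p was 0.00377, 0.0101, 0.0376 and 0.0426 in this order.

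The other 18 lists did not pass camera in this comparison. The adjusted p was 0.114 for Wnt signalling, 0.153 for protease inhibitors, 0.203 for proteases, 0.207 for inflammatory mediators, 0.224 for the unfolded protein response, 0.25 for both lymphocytes and TGF-beta and BMP signalling, 0.418 for proliferation and 0.453 for synovial and tendon fibroblasts. It was above 0.5 for glycolysis and hypoxia, osteoclasts, antioxidant, immediate-early, skeletal muscle, interferon, autophagy, macrophage and osteoblast genes. In 2 of them the signs disagreed: proliferation was tested as lower with a median of 0.02, and osteoblasts as higher with a median of -0.02.

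These counts, too, depend on the surgery term and the method. edgeR without the surgery term gave 0 genes past the threshold (1819 at an unadjusted p under 0.05, smallest adjusted p 0.0672, against 1872 with the term), DESeq2 with both terms gave 72, of which 52 were higher and 20 lower, and limma on log2(FPKM + 1) gave 0. Fits of 3 libraries without the surgery term gave 2 without the DMM library of M04 (Chil4 and Hbb-y), 331 without the DMM library of M05, 0 without the sham library of M04 and 58 without the sham library of M05. Of the 331, 200 were higher and 131 lower, and 179 were among the 341. With DESeq2 and without the DMM library of M05 more genes were thus higher than lower, against the main fit. Of the 42 named genes past the threshold, 26 moved by over 1.5 times in at least 1 of these fits. Of the 83 genes higher in DMM knees, 34 were also lower in M05, where independent lists would share 1.36, although the same 4 libraries enter both comparisons.

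**Figure D4:**
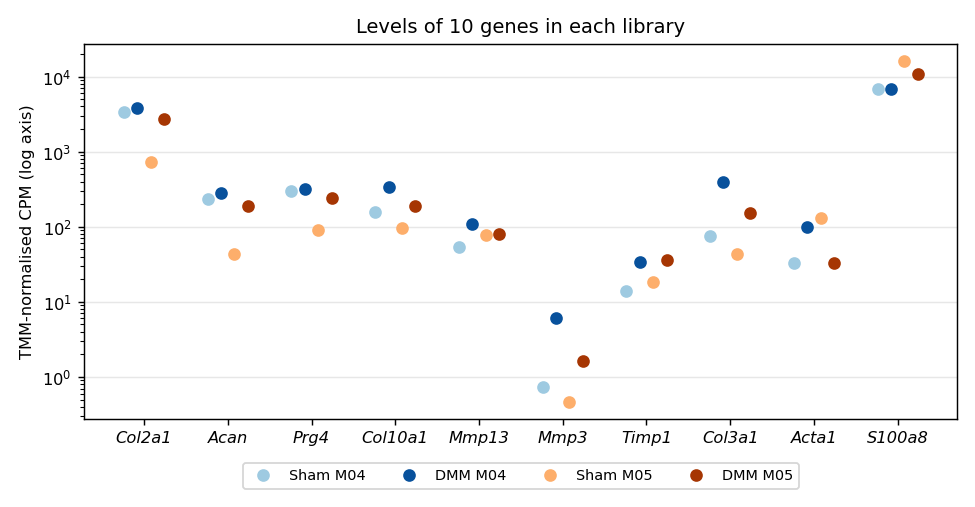
TMM-normalised CPM (y axis, log scale) of 10 genes; each point is 1 library, coloured by mouse and surgery. Col2a1, Acan and Prg4 are lowest in the sham library of M05, Col3a1 and Timp1 are higher in both DMM libraries than in the sham library of the same mouse, and Acta1 is highest in the sham library of M05.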

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

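For the skeletal muscle pattern, the limit for counting error was set after the result had been seen, and the second muscle list was written before its values were examined. The results below were flagged because the DMM to sham ratio was positive in M04 and negative in M05, and, in both mice, lay outside the central 95% of random lists for a list or was over 1.5 times for a gene. For the lists the difference between the mice was not tested. For single genes it was tested only without the mouse and surgery terms, since a model with both leaves no degree of freedom for it, and genes past an adjusted p of 0.05 in that test were flagged too.

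The skeletal muscle list moved from a ratio of 1.5 in M04 to -1.80 in M05, a difference of -3.30. The difference between the mice was -7.74 for Myh1, -3.73 for Mybpc2, -3.59 for Pvalb, -3.99 for Casq1, -3.58 for Acta1, -3.47 for Des, -3.31 for Ckm and -7.40 for Mb. In the test of the difference Mb and Acta1 passed (adjusted p = 0.0342 each), and the other 6 genes did not (0.115 for Des to 1.0 for Pvalb). The list of ribosomal proteins, with ratios of 0.09 and -0.20, differed by -0.30.

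Muscle tissue carried into the DMM library of M04 and the sham library of M05 was weighed first for the muscle genes. On a second list of muscle genes, 18 of 19 had a positive ratio in M04 and a negative one in M05, the exception being Cacng1. This fits the explanation, but any other cause that moves muscle genes together would give the same result, so the count cannot single out carried-in muscle. Counting error was excluded, because the muscle list summed to 14014 counts in the sham library of M05, against 3178 in its DMM library. Its share of all counts was 0.0676% (95% Wilson interval 0.0662 to 0.0690) in the DMM library of M04 and 0.0725% (0.0713 to 0.0737) in the sham library of M05, and 0.0250% in each of the others. The muscle genes followed neither the surgery nor the mouse alone. A response to surgery that differs between M04 and M05, through genotype or otherwise, would give the same pattern. It stays open beside carried-in muscle. The design cannot separate them, because no mouse has a repeated library of either kind of knee.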

How the results depend on the processing

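Scaling on the cartilage list, thinning, the length and GC offsets and the finite prior were chosen after seeing the data. The 85 genes for DMM against sham became 35 with RLE factors, 53 with library totals, 19 without haemoglobin and ribosomal protein genes, 13 with DESeq2, 0 without the mouse term, and 1 with limma on either form of the FPKM values. They became 0 with cartilage-list factors, 44 after thinning, 4 with length and GC offsets (Col3a1, Dpt, Col10a1 and Htra1), and 1, Col3a1, with a finite prior in limma. With the offsets all 83 higher genes kept their sign and 77 an unadjusted p under 0.05, and their median fold change was 0.957 against 0.965. The 341 genes for M05 against M04 became 186, 912, 59 and 72 with RLE factors, library totals, haemoglobin and ribosomal genes left out and DESeq2, the last with 52 higher and 20 lower against 126 and 215. They became 220 with limma-voom, 569 at an adjusted p of 0.1, 0 without the surgery term or with either form of the FPKM values, 1 with cartilage-list factors (Hbb-bh1) and 3 with length and GC offsets (Hbb-bh1, Chil4 and Col16a1). The split that groups the DMM library of M04 with the sham library of M05 gave 2 genes, Mb and Acta1, and is the test of a difference between the responses of the mice. With library totals 2.30% of the genes were higher in M05, against 37.0% with TMM, and the median of all genes shifted by -0.24. Prior degrees of freedom were infinite for 83.0% of genes with TMM, and had a median of 46.6 with RLE factors, 28.1 with library totals, 18.7 without haemoglobin and ribosomal genes and 10.7 with the offsets. Whether these differences in the prior account for the counts was not examined, and for each of these counts the cause was not tested.

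Leaving out each library in turn, in fits where the lone library is assumed to vary like the others, gave 0 to 121 genes for DMM against sham and 0 to 331 for M05 against M04, the 331 with 200 higher and 131 lower. The gene lists past the threshold, 10 for surgery and 12 for the mouse, ranged from 2 to 16 and from 5 to 15. With an estimated correlation, a form that could hardly pass any list on 1 residual degree of freedom, 0 lists passed in either comparison. The fry test gave 0 for surgery and 1 for the mouse, the synovial and tendon fibroblasts (adjusted p = 0.0225). Under the other settings 9 to 13 lists passed for surgery. Hbb-bh1 reversed to -4.31 without the DMM library of M05 and stood at 10.47 without its sham library. Prg4 reversed to -0.11 without the sham library of M05 and stood at 1.63 without that of M04. For M05 against M04, Col3a1 reversed to 0.35 without the DMM library of M04 and stood at -2.42 without that of M05. These fits have no term for the other factor, so the difference between the mice enters the surgery effect, and the reverse. Their values therefore do not measure the effect within a mouse or within 1 kind of knee. The other named genes past the threshold, 26 of 28 for surgery and 41 of 42 for the mouse, kept their sign in the 4 leave-one-out fits and in the up to 7 other settings run for them: RLE, upper-quartile and total scaling, no second term, DESeq2, FPKM + 1 and the length and GC offsets. The correlation between the responses of the mice stayed between -0.05 and -0.00. With 12712425 to 19336628 counts per library, genes of low level were measured with a large error, such as Mmp3 (0.469 to 6.02 CPM), whose SE was 0.64.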

Other observations

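The genes in this paragraph lie outside the rule and were chosen after their values were seen. In DMM against sham, the collagen VI chains Col6a1 (1.14), Col6a2 (1.17) and Col6a3 (0.96), which form the filaments around chondrocytes, rose, as did the small proteoglycan Dcn (0.96), the calcification inhibitor Mgp (0.97) and the matrix protein Tnn (2.47). In M05 against M04, Prg2 was higher by 0.78, Prg3 by 0.91, Ear1 by 0.78, Ear2 by 0.79, Ear6 by 0.96 and Ear7 by 0.97. Prg2 and Prg3 encode proteins of eosinophil granules, and no list of eosinophil genes was tested. The Ear genes are close copies of one another, so their single values are uncertain.

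The ribosomal RNA precursor Rn45s held 0.589% of the counts in the sham and 0.514% in the DMM library of M04, and 0.704% and 1.57% in those of M05. The embryonic globin Hbb-y had 802 counts in the sham library of M04 and 8, 2 and 1 in the DMM library of M04, the sham library of M05 and the DMM library of M05. In the FPKM table it stood at 1.79, 1.28, 0.281 and 0.199 in the same order, so its count in the sham library of M04 is uncertain. The count and FPKM tables differed by over 1 log2 unit for 2 of the 85 genes of the surgery comparison.

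The tests of cartilage amount on the 4 fixed lists and their higher genes, and of depth and of the length and GC trend as the whole cause, were chosen after the results they measure had been seen. For the genes higher in DMM knees, unequal amounts of cartilage and unequal depth of the libraries were weighed against an effect of surgery. Unequal amounts of bone or other tissues were not tested. With factors set on the cartilage list 0 of the 83 stayed past the threshold, but this scaling shifted the median of all genes by -0.88 and took the common dispersion from 0.0299 to 0.218, so it cannot tell. The M05 ratio exceeded the M04 ratio by a median of 1.2 in the cartilage list. It differed by a median of -0.25 in the 54 other genes of the fibrous matrix, hypertrophy, protease and inhibitor lists (95% signed-rank interval over genes, for the median of pairwise means, -0.36 to -0.08). In the 10 of these among the 83 it differed by 0.0158 (-0.54 to 0.34), against 1.2 (0.75 to 1.28) in the 11 higher genes of the cartilage list. The intervals take genes as independent, although all come from the same 4 libraries, and measure no spread between mice. Within this limit, the values argue against the amount of cartilage as the whole cause for these lists as sets. For single genes it stays open beside an effect of surgery, both for the other 73 and for the 10, of which 5 had the larger ratio in M05, among them Ctgf (by 0.66) and Fn1 (by 0.49). After thinning to the smallest total 44 of 83 (53.0%) stayed past the threshold as the median SE went from 0.19 to 0.22, a count that cannot tell. All 83 kept their sign, and their median fold change was 0.95 against 0.96. Random thinning leaves each gene's expected share of its library unchanged, so the kept folds cannot exclude unequal totals either.

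For the genes that differ between M05 and M04, a trend with transcript length and GC content and a lower amount of cartilage were weighed. With the trend removed 3 of 341 stayed past the threshold, but 290 kept an unadjusted p under 0.05 and all kept their sign, so this cannot tell how far the trend contributes. The median went from -0.78 to -0.63 (median SE of a gene 0.18) for the lower and from 0.62 to 0.46 (0.15) for the higher genes. These genes were picked for their differences in the same libraries, which by itself keeps such medians away from 0. The kept medians thus cannot exclude the trend as the whole cause. Per doubling of length the slope was 0.099 and 0.091 in the sham and DMM libraries of M04, and -0.099 and -0.092 in those of M05. Of the 215 lower genes, 104 (48.4%) were also lower in the DMM than in the sham library of M05, although cartilage transcripts were higher there. This argues against less cartilage as the cause for all 215. It does not exclude it, because the count rests on 1 pair of libraries, takes in falls of any size, and a fall with surgery could hide a rise. Whether the animals differ in genotype could not be tested with 1 mouse each.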
